A study of Rattus norvegicus with 32 samples.

How the data were processed

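RNA from normal mammary gland of rats was hybridised to 1 Affymetrix rat array per sample. The 30 single-sample arrays fell into 6 groups of 5, which were the inbred strains Cop, F344, ACI, BUF/N and WF and the F1 hybrid of Cop and F344, and the remaining 2 arrays were labelled as a Cop pool and an F344 pool. Groups were taken from the labels. Per the labels, RNA was extracted with an RNeasy Maxi kit, precipitated with lithium chloride and checked for integrity, and biotinylated cRNA was made from 5 µg of total RNA. The labels give no age, sex, stage of the oestrous cycle, time of collection or batch.

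The deposited values were linear signals that the authors computed with Affymetrix Microarray Suite 5.0, at 8799 probe sets per array, 59 of them controls. After trimming the lowest and highest 2% of probe sets, the mean signal lay between 250.3 and 250.4 on all 32 arrays, so each array had been scaled to one target, and no other normalization between arrays was seen. Median signals per array ran from 65.8 to 102, a ratio of 1.55, which was above the limit of 1.5 set for it. By the rule set for this case the arrays were scaled again to a common trimmed mean. As the trimmed means were already equal, the factors were 0.9997 to 1.0002 and this left the medians as they were, those of ACI 2 and ACI 5 included. Signals printed are the deposited ones. Counts of molecules do not exist for arrays, and the number of arrays limits the precision.

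Signals below the 25th percentile of all values (18.3) were set to that floor and log2 transformed. A probe set was tested when at least 5 of the 30 arrays lay above the overall median of 78.4, which left 5040 probe sets. Gene symbols came from the table supplied with the array and from a gene table matched by identifier for 6994 probe sets. In all, 7018 probe sets had 1 symbol, 308 several and 1473 none. The tested probe sets with 1 symbol numbered 4202 and covered 3054 genes, and 838 tested ones had several symbols or none.

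Group means were fitted with limma 3.58.1 in R 4.3.3, with a trend in the variance and 29.58 degrees of freedom per contrast, and p-values were adjusted by the Benjamini-Hochberg method within each contrast at a threshold of 0.05. The contrasts were each pair of the 6 groups, F1 against the mean of its parents, each inbred strain against the mean of the other 4, and Cop and F1 against F344, BUF/N and WF. The sides of the last contrast came from background knowledge and not from the labels, and ACI was left out of it. A probe set was called apart in a strain when it passed against each of the other 4 inbred strains in the same direction. The 2 pools were left out of the fits and compared as 1 ratio, without a test.

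The genes named were chosen by a rule. Such genes had to pass the test, have no overlap between the signals of the groups and have a probe set with 1 symbol, and were ranked by the size of the change. Up to 12 in each direction were named for Cop against F344, 6 for each strain (ranked by the smallest of its 4 changes), 5 for F1 (with no overlap rule), and 8 for the last contrast. Members of the gene lists with the smallest adjusted p, and 18 genes set in advance whatever their result, were named as well. For each gene ranked by its change the probe set with the largest change was used. For list members and the genes set in advance it was the probe set with the highest mean signal. Other probe sets of the gene that gave another direction are reported. Of the genes chosen by this rule, 1 is not reported here. A fold against a group wholly at the floor is given as a lower bound.

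In addition, 30 lists of pathway genes and cell type markers were tested in 8 contrasts with camera of limma, with 1 probe set per gene and a preset correlation of 0.01, and p-values were adjusted over the 30 lists of a contrast. Each list was tested again with a correlation estimated from the arrays. The mean of a list over its members on each array, centred on all arrays, is called its score. The threshold, filter, contrasts, gene lists and rule for names were set before the data were examined. The fitting steps were tested on simulated data in which known probe sets were changed. There, 31.3%, 82.1% and 100% of the probe sets changed 1.5, 2 and 4 fold between Cop and F344 were recovered, with 5 others called. For probe sets set apart in Cop these shares were 19.4%, 70.1% and 95.5%, with 0 others called. Only probe sets whose mean log2 signal lay above that of a signal of 100 were changed. The simulated noise was independent between arrays and probe sets and had the same spread in every group. The shares therefore do not hold for dimmer probe sets or for arrays that vary together.

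The alternatives tried were floors at the 10th and 40th percentile, an offset of 50, no filter, a filter of 15 arrays, quantile normalization, centring on the median, replicate number as a block, array weights, no variance trend, the pools as sixth samples, only the arrays compared, a threshold of 0.01, an estimated correlation for the lists and leaving out each array in turn. The arrays F1 2, F1 3, ACI 2 and ACI 5 were left out as an alternative added after the data were seen, as was the midpoint of the parental signals. Replicate numbers were checked for pairing. Of 75 pairs of arrays with the same number, 16 correlated above 0.1, and in 0 of the 15 pairs of groups did all of them, so samples were treated as unpaired.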

Results

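The 6 groups compared were the normal mammary glands of the rat strains Cop, F344, ACI, BUF/N and WF and of the F1 hybrid of Cop and F344, with 5 arrays each. The title of the series asks about inherited susceptibility to mammary cancer. Cop is known as a strain that resists chemically induced mammary cancer and passes this on dominantly to its hybrids, and F344, BUF/N and WF are known as susceptible. The labels do not say that the samples of a group came from separate animals, so the p-values measure the spread between these samples. Across the tested probe sets, arrays of the same group correlated with r = 0.846 to 0.978 (median 0.947) and arrays of different groups with r = 0.788 to 0.954, where probe sets are not independent replicates. F1 2 and F1 3 correlated with the other F1 arrays at r = 0.846 to 0.893 and with each other at 0.959. ACI 2 and ACI 5 correlated with the other ACI arrays at r = 0.876 to 0.914 and with each other at 0.951, and their median signals were the highest of the series. The ratio of 3' to 5' signal of the GAPDH control ran from 0.868 to 1.35 over the 30 arrays, and that of the actin control from 1.01 to 1.98. The actin ratio was 1.78 in ACI 2 and 1.80 in ACI 5, and from 1.19 to 1.34 in the other ACI arrays. Within F1 it was lowest in F1 3 (1.27) and F1 2 (1.49) and highest in F1 1 (1.98).

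Among the genes that separated the groups, Hs6st1, a heparan sulfate sulfotransferase, had a signal of 8.78 ± 2.54 (SD, n = 5) in Cop and 455.4 ± 66.9 (SD, n = 5) in F344. Lcn2, a secreted lipocalin of epithelia, was low in F344 and ACI and high in the other 4 groups. Of the 5040 probe sets tested, 2613 (51.8%) differed among the 6 groups in limma's F test. BUF/N and WF differed at 112 probe sets, the lowest number of the 15 pairs, followed by Cop and F344 with 174 and ACI and WF with 362. The highest number was 1596, for F344 and F1. All pairs shared the same estimate of the spread between arrays. That spread was unequal, with arrays correlating at r = 0.846 to 0.978 within F1 and 0.964 to 0.973 within F344. The order of the pairs is therefore no exact measure of distance, and some counts changed with only the arrays compared, as given below.

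**Figure D1:**
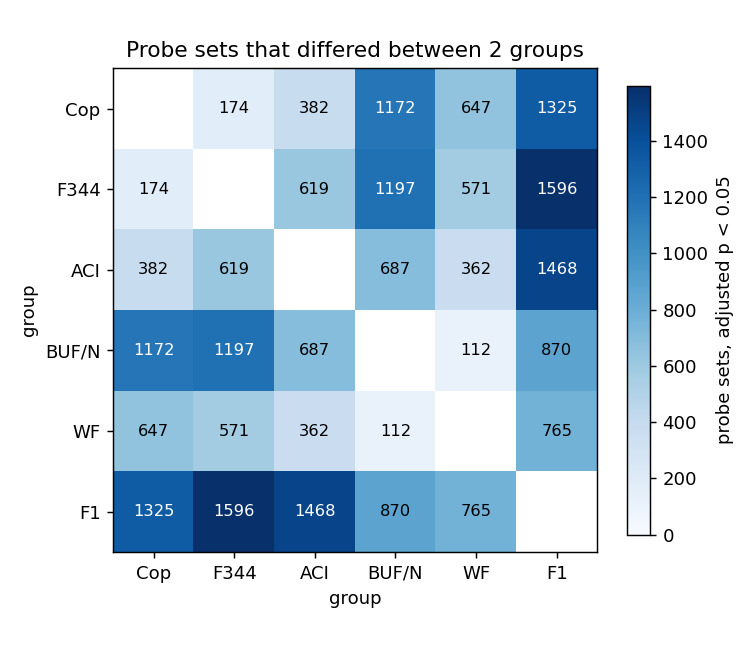
Number of probe sets that passed an adjusted p of 0.05 in limma for each of the 15 pairs of groups with 5 arrays each. The pair of BUF/N and WF had 112 and the pair of F344 and F1 had 1596. All pairs shared the same estimate of the spread between arrays.

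Cop was compared with F344 because these are the resistant and susceptible parents of the hybrid. Lcn2 was the gene highest in Cop, with a signal of 1616 ± 395 (SD, n = 5) against 72.3 ± 20.3 (SD, n = 5) in F344 (log2 change 4.50, SE 0.332, adjusted p = 5.23e-11). Tmtc3, a mannosyltransferase of the endoplasmic reticulum, was at 413.9 ± 91.6 against 58.4 ± 8.74 (log2 change 2.81), and Jund, a member of the AP-1 transcription factors, was higher by 2.74 on the log2 scale, with 3 of the 5 F344 arrays at the floor. Alb, which encodes serum albumin (2.68), the growth factor gene Bmp3 (144.7 against 37), the kinesin gene Kif13a (1.86), the lipid phosphatase gene Plpp1 (1.79), the platelet chemokine gene Pf4 (1.26) and the adenylate cyclase gene Adcy5 (1.25) were higher in Cop as well. Lsamp, a neural adhesion gene, was higher by 1.57, Sorbs2, an adaptor of the cytoskeleton, by 1.43, and Sfxn1, a mitochondrial serine transporter, by 1.30. The call of Lsamp ended without Cop 5 (adjusted p = 0.064), F344 4 (0.057) or F344 5 (0.071). The call of Sorbs2 ended without Cop 1 (0.057), Cop 2 (0.089), F344 3 (0.084) or F344 5 (0.098), and that of Sfxn1 without any 1 of the Cop and F344 arrays other than F344 3, with adjusted p from 0.056 to 0.12.

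On its named probe set, Hs6st1 was at least 24.7-fold lower in Cop than in F344, with all 5 Cop arrays at the floor (log2 change -4.63, SE 0.179, adjusted p = 3.96e-18). Fgg, which encodes a chain of fibrinogen, was at least 16.8-fold lower and the proteoglycan gene Spock2 at least 6.1-fold lower, again with Cop at the floor. Ephx2, the soluble epoxide hydrolase, was at 20.4 ± 20.5 (SD, n = 5) in Cop and 229.2 ± 56.9 (SD, n = 5) in F344 (log2 change -3.29), with 4 of the 5 Cop arrays at the floor, so that the size of its change is set in part by the floor. Cbr1, a carbonyl reductase that acts on xenobiotics, was at 221.5 ± 83.4 against 1793 ± 630 (log2 change -3.02). Grifin, a galectin-related gene (-2.96), Fhl2, a transcriptional cofactor (-2.68), the imprinted RNA H19 (-2.02), the lysosomal activator gene Gm2a (-1.98), the complement regulator gene C4bpa (-1.91) and the hexokinase gene Hk2 (-1.90) were lower too. The call of H19 ended without Cop 2 (adjusted p = 0.071) or Cop 5 (0.057). Other probe sets gave smaller changes for Fgg (-1.35), for Hk2 (-0.31), for Adcy5 (0.14) and for Sorbs2 (0.57 and 0.20), and Ephx2 had -3.02, -2.87 and -0.78.

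In all, 174 probe sets passed between Cop and F344, 85 higher in Cop and 89 lower, with 35 and 55 of them beyond 2-fold. At an unadjusted p under 0.05 there were 709. The number was 479 with array weights, 292 with only the arrays of Cop and F344, and 290 without F1 2, F1 3, ACI 2 and ACI 5. Of the 90 that had another tested probe set for the same gene, 49 had one called in the same direction, 2 one called in the opposite direction and 39 none called. The opposite pair belonged to Gstt2, a glutathione transferase gene. The call of Lsamp also ended with the floor at the 10th percentile, that of Adcy5 with the floor at the 40th, that of Sorbs2 with the floor at the 40th, the offset or no filter, and that of Sfxn1 with no filter or quantile normalization.

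**Figure D2:**
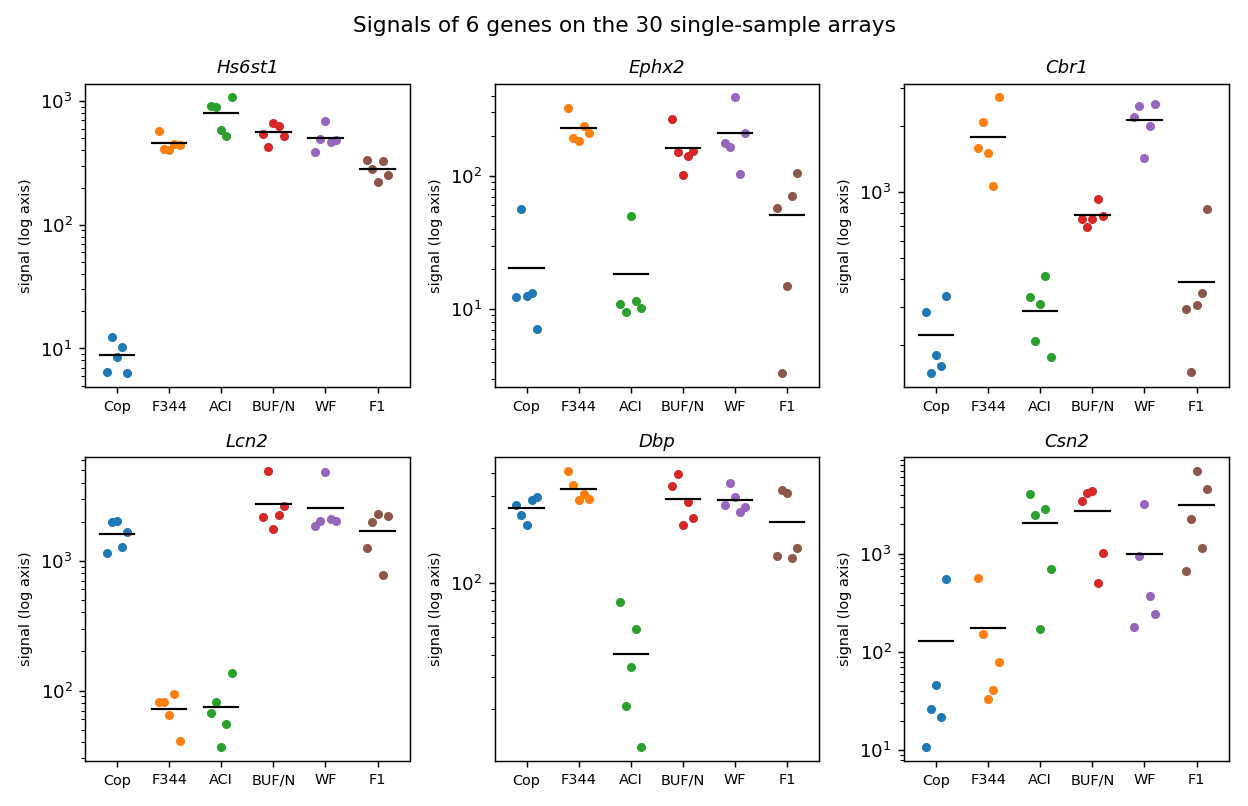
Deposited signals (log axis) of Hs6st1, Ephx2, Cbr1, Lcn2, Dbp and Csn2 on the 30 single-sample arrays by group, where points are arrays and lines are means of 5. The Cop arrays sit lowest for Hs6st1 and the ACI arrays lowest for Dbp, with means of 8.78 and 40.3.

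The lists that differed between Cop and F344 concerned lipid synthesis, epithelium, muscle and immune cells. Of 21 tested genes of fatty acid and sterol synthesis, 3 were lower in Cop and 0 higher, and 3 and 0 when adjusted over the list alone, with Acaca, the first enzyme of fatty acid synthesis, at -1.23 (camera adjusted p = 0.00027, and adjusted p = 0.4 with an estimated correlation). Of 10 luminal epithelial markers, 2 were lower, among them the tight junction gene Cldn3 (-1.29), and Lcn2 was higher, and 8 were lower and 1 higher when adjusted over the list alone (adjusted p = 0.00087, and adjusted p = 0.44 with an estimated correlation). None of 18 skeletal muscle genes passed, 0 when adjusted over the list alone, while their median was -1.33 (adjusted p = 0.00087, and adjusted p = 0.54 with an estimated correlation). That call ended without Cop 2 (adjusted p = 0.069). Of 4 mast cell genes, the tryptase gene Tpsab1 was higher (0.93), and 2 were when adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.4 with an estimated correlation). The 13 cell cycle genes had a median of 0.57 (adjusted p = 0.01, and adjusted p = 0.54 with an estimated correlation), with 0 genes passing on either count. The 9 T lymphocyte genes had a median of -0.57 with 0 passing on either count (adjusted p = 0.011, and adjusted p = 0.54 with an estimated correlation), and this call ended without Cop 1 (0.053) or Cop 4 (0.078). The muscle score was 0.40 ± 1.72 (SD, n = 5) in Cop and 1.61 ± 0.77 in F344, a spread between arrays as large as the difference. The list of secretoglobin and glandular genes had a median of -0.24 and a mean of 0.75 and the list of oestrogen and progesterone response a median of 0.05 and a mean of -0.41, and both missed the threshold.

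The Cop pool stood against the F344 pool as the single samples did for the named genes, with log2 ratios of 4.18 for Lcn2 and -2.61 for Cbr1. For Hs6st1 (8.1 against 493.4), Fgg (9.7 against 333.3) and Ephx2 (9.6 against 186.9) the Cop pool was below the floor, so their log2 ratios of -4.75, -4.19 and -3.35 are lower bounds of the difference. Of the 174 probe sets that passed between Cop and F344, 173 had the same sign in the pools. The ratios of the pools and of the samples correlated with r = 0.658 over all tested probe sets and r = 0.962 over the 174. The pools were single arrays and may hold the same animals, so no test was made.

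Genes that set Cop apart from each of the other 4 inbred strains show what is particular to Cop among them. A single strain cannot link such genes to resistance. Hs6st1 was at least 24.7-fold lower on its named probe set than in any of them (log2 change -4.63 or beyond, adjusted p at most 4e-18). This is a value of a single probe set with the Cop arrays at the floor. Probe sets of the same gene can differ in direction between strains, as those of RT1-Bb did (see BUF/N below). Msx1, a homeobox gene, was at 66.5 ± 21.4 (SD, n = 5), a change of at least -1.13 against each strain, and the purinergic receptor gene P2rx4 (-0.77) and the cytoskeletal adaptor gene Abi2 (-0.74) were lower as well. Plpp1 was highest in Cop, at 541.2 ± 102 (SD, n = 5), by 0.88 or more, as was Milr1, an inhibitory receptor of mast cells, by 0.75 or more. These 6 genes stayed apart whichever of the 30 arrays was left out. Lsamp (1.57 or more) stayed apart in 27 of the 30 such fits, the integrin gene Itga7 (0.69) in 26, Sfxn1 (1.30) and the RNA editing gene Apobec1 (0.68) in 21 each, the prolactin receptor gene Prlr (-0.62) in 20 and the collagen gene Col2a1 (-1.03) in 16. Another probe set of Plpp1 gave a smaller change against the mean of the other 4 strains (0.31). F1 was not part of this comparison, and is given here on a scale with F344 at 0 and Cop at 1. It was at 0.15 for Hs6st1, -0.47 for Msx1, 0.12 for P2rx4 and 0.29 for Abi2. For Plpp1 F1 was at 0.58, for Milr1 at 0.72, for Lsamp at -0.42 and for Itga7 at 0.11. For Sfxn1 it was at -0.47, for Apobec1 at 0.68, for Prlr at 0.14 and for Col2a1 at -0.97.

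In all, 36 probe sets were apart in Cop, 16 higher and 20 lower. The number was 22 without Cop 1, 19 without Cop 2 and 20 without Cop 4 or F344 4. In pairs, Cop differed from ACI at 382 probe sets, 165 higher in Cop and 217 lower, from BUF/N at 1172 (557 and 615) and from WF at 647 (283 and 364). The number for ACI was 213 without Cop 1, 217 without Cop 2 and 226 without ACI 2. It was 228 without both ACI 2 and ACI 5, 626 without F1 2 and F1 3 and 584 with the pools as sixth samples. The balance of directions depended on the scaling in all 3 pairs. Quantile normalization moved the median change of all genes between Cop and ACI by 0.105 and centring by 0.112, and the percentage of calls higher in Cop was then 63 and 68.9, against 43.2. Against BUF/N, 633 probe sets were higher in Cop and 540 lower with quantile normalization, and 681 and 490 with centring. Against WF these numbers were 329 and 319, and 381 and 275.

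In Cop, genes of milk proteins and of the epithelium were lower and genes of fat cells higher than in the mean of the other 4 strains. Of 9 milk protein genes, 4 were lower and 0 higher, 5 and 0 when adjusted over the list alone, with the caseins Csn2 at -3.66 (SE 0.763) and Csn3 at -2.52, the whey protein Wap at -3.42 and the mucin Muc1 at -0.95 (camera adjusted p = 0.00015, and adjusted p = 0.17 with an estimated correlation). Of 10 luminal markers 8 were lower and 1 higher, the same numbers when adjusted over the list alone, with Cldn3 at -1.43 and Cldn7 at -0.96 (adjusted p = 1.6e-05, and adjusted p = 0.14 with an estimated correlation). Of 10 basal and smooth muscle markers 7 were lower, 7 lower and 1 higher when adjusted over the list alone, among them the contractile genes Cnn1 (-0.79) and Tagln (-0.58), with adjusted p = 0.003, and adjusted p = 0.14 with an estimated correlation. Of 17 adipocyte genes 5 were higher, 9 when adjusted over the list alone, with the lipid droplet gene Plin1 at 0.95, the adrenergic receptor gene Adrb3 at 0.83 and the carbonic anhydrase gene Car3 at 0.64 (adjusted p = 6.1e-06, and adjusted p = 0.14 with an estimated correlation). Of 34 genes of oxidative phosphorylation and beta oxidation 4 were higher on both counts, among them Etfa at 0.59 (adjusted p = 0.00074, and adjusted p = 0.15 with an estimated correlation). Of 8 macrophage genes 3 were higher on both counts, with the lectin gene Clec10a at 0.88 and the complement gene C1qb at 0.64 (adjusted p = 0.003, and adjusted p = 0.15 with an estimated correlation). Of 4 mast cell genes 2 were higher on both counts (adjusted p = 0.014, and adjusted p = 0.15 with an estimated correlation). This call ended without Cop 4 (0.052). The score of the luminal markers was -0.53 ± 0.39 (SD, n = 5) in Cop, -0.34 in F344 and -0.44 in ACI. Lcn2 did not follow the other markers, and without it the scores were -0.73 ± 0.40 in Cop, -0.02 in F344 and -0.13 in ACI. The score of the fat cell genes was 0.40 ± 0.15 in Cop and that of the muscle genes 0.40 ± 1.72.

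In F344, Grifin was highest, at 1145 ± 201 (SD, n = 5), with a log2 change of 2.56 or more against each of the other 4 strains (adjusted p at most 3.4e-11). The MHC class II gene RT1-Db1 (1.58), the aldo-keto reductase gene Akr1c3 (1.27), the membrane receptor gene Paqr3 (1.13) and the prostacyclin synthase gene Ptgis (0.91) were higher as well. Kif13a was lowest in F344, at 74.6 ± 2.66 (SD, n = 5) and by -1.73 or beyond, and the securin gene Pttg1 (-1.15), the kinase adaptor gene Azi2 (-0.88), the chaperone gene Hyou1 (-0.86) and Tmtc3 (-0.75) were lower too. In all, 25 probe sets were apart in F344, 7 higher and 18 lower, and 16 without F344 5. Ptgis was no longer apart without Cop 1, and Tmtc3 stayed apart in 16 of the 30 fits that left out an array.

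Muscle genes were higher in F344 than in the mean of the other 4 strains, with 9 of 18 passing and 16 when adjusted over the list alone (median 1.999, camera adjusted p = 1.2e-07, and adjusted p = 0.4 with an estimated correlation). With them, 5 of 21 genes of fatty acid and sterol synthesis were higher, 6 when adjusted over the list alone, with Acaca at 1.07 and the malic enzyme Me1 at 1.37 (adjusted p = 0.00067, and adjusted p = 0.32 with an estimated correlation). Of 34 genes of oxidative phosphorylation 2 were higher on both counts (adjusted p = 0.00067, and adjusted p = 0.32 with an estimated correlation). Of 13 cell cycle genes 6 were lower, 9 when adjusted over the list alone (median -0.62, adjusted p = 0.00094, and adjusted p = 0.42 with an estimated correlation). Of 8 clock genes 2 were higher, 5 when adjusted over the list alone, with the repressor gene Bhlhe41 at 0.49 (adjusted p = 0.032, and adjusted p = 0.32 with an estimated correlation). It was lost without F344 1 (0.088). The clock score was 0.34 ± 0.13 (SD, n = 5) in F344, between 0.16 and 0.27 in Cop, BUF/N and WF, and -0.79 in ACI, so the low ACI group made up most of this difference. Of 8 macrophage genes 1 was higher, 2 when adjusted over the list alone (adjusted p = 0.032, and adjusted p = 0.4 with an estimated correlation). The list missed the threshold without F344 2 (0.074). Of 4 red cell genes 2 were higher, 3 when adjusted over the list alone, with the globin gene Hbb at 1.09 (adjusted p = 0.038, and adjusted p = 0.42 with an estimated correlation). The red cell call ended when F344 1 (0.1), F344 4 (0.066), ACI 1 (0.063), ACI 4 (0.053) or F1 2 (0.051) was left out.

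In ACI, genes of the daily clock were low. Dbp, a transcription factor with a strong daily rhythm, was at 40.3 ± 26.8 (SD, n = 5), with a log2 change of -2.85 or beyond against each of the other 4 strains (adjusted p at most 1.5e-07), and the clock gene Per2 was lower by -1.60 or beyond. The eosinophil chemokine gene Ccl11 (-1.50), the biliverdin reductase gene Blvra (-1.11), the mitochondrial ribosomal gene Mrpl52 and the thiolase gene Acaa2 were lower as well, and Tnfrsf11b, which encodes osteoprotegerin, was higher by 1.13 or more. Nae1 was higher by 0.81 or more, but its other probe set gave -0.07 against the mean of the other 4 strains. Pdp2 (0.82) stayed apart in 15 of the 30 fits that left out an array. In all, 37 probe sets were apart in ACI, 13 higher and 24 lower. The number was 22 without ACI 2 or ACI 5, 57 without ACI 3, and 13 without both ACI 2 and ACI 5.

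Of 8 clock genes, 5 were lower in ACI than in the mean of the other 4 strains and 0 higher, 6 and 0 when adjusted over the list alone, with a median of -0.95 and with the repressor genes Bhlhe40 at -1.03 and Bhlhe41 at -0.95. The camera adjusted p was 4e-08, and adjusted p = 8.9e-05 with an estimated correlation, the single list call of the 8 contrasts that held with it. Of 18 MHC genes 7 were lower and 1 higher, 9 and 2 when adjusted over the list alone, with RT1-DMb at -0.81 (adjusted p = 0.00044, and adjusted p = 0.27 with an estimated correlation). Of 27 genes of xenobiotic metabolism 5 were lower on both counts, with Cbr1 at -1.67 and the epoxide hydrolase Ephx1 at -1.16 (adjusted p = 0.00055, and adjusted p = 0.27 with an estimated correlation). Of 13 cell cycle genes 3 were higher, 6 when adjusted over the list alone, with the replication gene Mcm5 at 1.18 (adjusted p = 0.00055, and adjusted p = 0.42 with an estimated correlation), though Mcm5 missed the threshold without ACI 2 and ACI 5 (adjusted p = 0.074). Of 8 macrophage genes 2 were lower, 5 when adjusted over the list alone (adjusted p = 0.00044, and adjusted p = 0.16 with an estimated correlation). Of 4 red cell genes 2 were lower, 3 lower and 1 higher when adjusted over the list alone, with Hbb at -1.56 (adjusted p = 0.0051, and adjusted p = 0.27 with an estimated correlation). Of 4 secretoglobin and glandular genes 2 were lower and 1 higher on both counts, with Lcn2 at -3.72 (adjusted p = 0.02, and adjusted p = 0.16 with an estimated correlation). This call ended without ACI 4 (0.066). Lcn2 was also the 1 gene of 10 luminal markers that was lower on both counts (adjusted p = 0.017, and adjusted p = 0.42 with an estimated correlation). It was lost without ACI 2 (0.074). Of 35 ribosomal protein genes 2 were lower and 1 higher on both counts (adjusted p = 0.0044, and adjusted p = 0.42 with an estimated correlation). This call ended under quantile normalization (0.53).

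In BUF/N, RT1-Bb, a beta chain of MHC class II, was at 1753 ± 641 (SD, n = 5) on the probe set named by the rule, at least 90.5-fold above each of the other strains, whose arrays were all at the floor. Of its other probe sets, 1 was lower in BUF/N by -2.95 against the mean of the other 4 strains and the others higher by 0.80 and 3.20. On the one higher by 0.80 every strain had a clear signal, at 837.7 in Cop, 767.1 in F344, 656.5 in ACI, 1363 in BUF/N and 1012 in WF. The 90.5-fold is thus a value of 1 probe set and not of the gene. The kinase subunit gene Pik3r1 was at 597 ± 124 (SD, n = 5), and the transcription factor gene Foxq1 was higher as well. Lower were Mst1, which encodes a kringle protein of plasma, at 53.8 ± 40 (SD, n = 5), the matricellular gene Ccn1, the tetraspanin gene Tspan8 (at least 4.41-fold against the mean of the other 4), the mast cell protease gene Mcpt1l1, the glutamate transporter gene Slc1a3 and the fibulin gene Efemp1. Other probe sets of Mcpt1l1 and Efemp1 gave smaller changes (-0.26 and -0.35). The sodium channel gene Scnn1b was apart in BUF/N too but stayed so in 8 of the 30 fits that left out an array. In all, 34 probe sets were apart in BUF/N, 10 higher and 24 lower. The number was 22 without BUF/N 3 or BUF/N 4, 72 without WF 1 and 21 without WF 4.

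Milk protein and epithelial genes were higher in BUF/N than in the mean of the other 4 strains. Of 9 milk protein genes 4 were higher, 5 when adjusted over the list alone, with Csn2 at 3.06, Wap at 2.87 and Csn3 at 1.48 (camera adjusted p = 0.002, and adjusted p = 0.34 with an estimated correlation). Of 10 luminal markers 8 were higher, 9 higher and 1 lower when adjusted over the list alone, with Lcn2 at 2.81, Cldn3 at 1.01 and the protease inhibitor gene Spint2 at 0.79 (adjusted p = 5.3e-05, and adjusted p = 0.16 with an estimated correlation). Of 4 secretoglobin and glandular genes 1 was higher, 3 when adjusted over the list alone (adjusted p = 0.0067, and adjusted p = 0.082 with an estimated correlation). Of 4 mast cell genes 2 were lower, 4 when adjusted over the list alone, with the carboxypeptidase Cpa3 at -1.45 and the chymase Cma1 at -0.92 (adjusted p = 0.00015, and adjusted p = 0.072 with an estimated correlation). Of 34 genes of oxidative phosphorylation 7 were lower, 11 lower and 1 higher when adjusted over the list alone, with Etfa at -0.72 (adjusted p = 0.0041, and adjusted p = 0.3 with an estimated correlation). Of 12 genes of p53 and apoptosis 3 were higher on both counts, with the caspase gene Casp6 at 0.81 (adjusted p = 0.035, and adjusted p = 0.3 with an estimated correlation). The list missed the threshold without ACI 5 or WF 3 (0.053 each). Of 17 adipocyte genes 6 were lower, 8 when adjusted over the list alone (adjusted p = 0.0096, and adjusted p = 0.35 with an estimated correlation). This call ended without BUF/N 3 (0.069). Of 18 muscle genes the myosin gene Myh1 was lower on both counts, at -1.01 (adjusted p = 0.0067, and adjusted p = 0.61 with an estimated correlation). It was lost without BUF/N 3 (0.055) or BUF/N 5 (0.096).

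In WF, Gp2, which encodes a glycoprotein of secretory cells, was at 914.6 ± 199 (SD, n = 5), against 134.9 ± 70.8 in Cop, 60.6 ± 30.7 in F344, 96.7 ± 52.5 in ACI and 59 ± 35.1 in BUF/N. The proteasome gene Psmb4 was at 1884 ± 178 (SD, n = 5), a log2 change of 1.10 against the mean of the other 4 strains, while its other probe sets gave 0.28 and 0.08. Vat1, a gene of vesicle membranes, was lower by -1.13 (another probe set gave -0.82). The flavoprotein gene Etfdh was at least 5.3-fold lower, and its other probe sets gave -0.15 and -0.29. The calcium binding gene Rcn3 (-1.85, other probe set -0.03) and Gstt2 (-2.28, other probe set 0.01) were lower on 1 probe set alone. Gsta4 was no longer apart when Cop 2, Cop 4, WF 2 or WF 5 was left out, and the lipase gene Lpl and Mmrn1 stayed apart in 23 of the 30 such fits. In all, 19 probe sets were apart in WF, 7 higher and 12 lower, and 11 without WF 5. Of 12 with another tested probe set, 7 had none called.

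In WF the epithelial lists were higher than in the mean of the other 4 strains. Of 10 luminal markers 3 were higher, 8 when adjusted over the list alone, with Lcn2 at 2.68 (camera adjusted p = 1.5e-05, and adjusted p = 0.14 with an estimated correlation). Of 10 basal and smooth muscle markers 5 were higher, 6 higher and 1 lower when adjusted over the list alone, with the myosin gene Myh11 at 0.87 and Tagln at 0.63 (adjusted p = 0.00035, and adjusted p = 0.089 with an estimated correlation). Of 18 muscle genes 1 was lower, 14 lower and 1 higher when adjusted over the list alone (median -1.50, adjusted p = 8.8e-07, and adjusted p = 0.38 with an estimated correlation). Of 34 genes of oxidative phosphorylation 2 were lower on both counts (adjusted p = 0.0041, and adjusted p = 0.38 with an estimated correlation). Of 3 brown fat genes Cidea was lower, at -0.70, and 2 were when adjusted over the list alone (adjusted p = 0.0093, and adjusted p = 0.14 with an estimated correlation). Of 21 genes of fatty acid and sterol synthesis 5 were lower, 6 when adjusted over the list alone, with the cholesterol gene Dhcr7 at -1.28 and the sterol sensor gene Insig1 at -0.72 (adjusted p = 0.015, and adjusted p = 0.38 with an estimated correlation). Of 17 adipocyte genes 2 were lower, 3 when adjusted over the list alone, with the glycerol channel gene Aqp7 at -1.02 (adjusted p = 0.0092, and adjusted p = 0.38 with an estimated correlation). Both of the last calls ended without WF 4 (0.061 each). The score of the luminal markers was 0.40 ± 0.21 (SD, n = 5) in WF and 0.51 ± 0.19 in BUF/N, or 0.24 and 0.35 without Lcn2, and that of muscle genes -0.90 ± 1.26 and -0.47 ± 1.18.

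**Figure D3:**
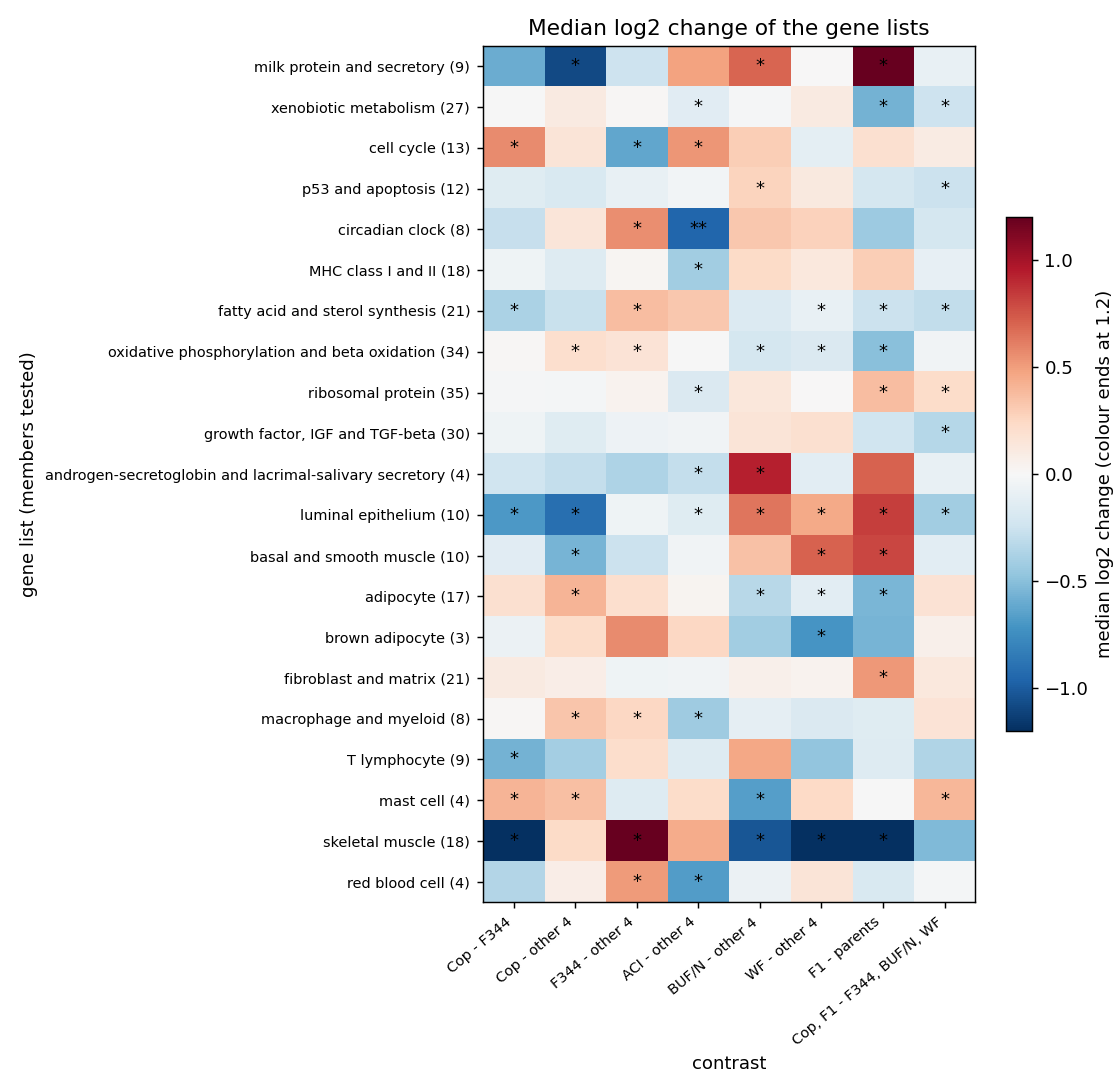
Median log2 change of the members of each gene list (colour scale) in each of 8 contrasts. The clock genes are lowest in ACI, with a median of -0.95, and the muscle genes lowest in F1, with a median of -2.32.

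The F1 hybrid was compared with the mean of its parents to see where it departed from their mean, which a gene at the level of 1 parent can also do. Csn2 was at 3110 ± 2610 (SD, n = 5) in F1, 131.2 ± 235 in Cop and 175.6 ± 227 in F344 (log2 change 5.00, SE 0.836, adjusted p = 5.3e-05). Scnn1b (2.25), the sugar phosphate transporter gene Slc37a1 (2.24), Gp2 (2.18) and the netrin receptor gene Neo1 (2.13) were higher too. Scd, a fatty acid desaturase, was at 70.7 ± 25.4 (SD, n = 5) in F1, 441 ± 206 in Cop and 661.2 ± 253 in F344 (log2 change -2.91, and -1.06 on its other probe set). The leukocyte phosphatase gene Ptprc (-2.32), the growth hormone receptor gene Ghr (-1.99), the respiratory chain gene Ndufb6 (-1.98) and the organic cation transporter gene Slc22a3 (-1.95) were lower. The other probe sets gave -0.27 each for Ptprc, -0.66 and -0.38 for Ghr, -0.71 for Ndufb6 and -1.14 for Slc22a3. In all, 1774 probe sets passed, 874 higher and 900 lower, with 103 and 296 of them beyond 2-fold. F1 differed from Cop at 1325 probe sets, and at 661 with only the arrays of these 2 groups, and from F344 at 1596. Without F1 2 and F1 3, the numbers were 1032 against the parental mean, among them 787 of the 1774, and 922 against F344. Of 779 called probe sets with another for the same gene, 418 had one called in the same direction, 49 one called in the opposite direction and 312 none called.

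At the 174 probe sets that differed between the parents, F1 lay between them at 99, beyond Cop at 34 and beyond F344 at 41, and it passed against both parents at 29. On a scale with F344 at 0 and Cop at 1, the median position of F1 was 0.45, and 0.37 without F1 2 and F1 3. Hs6st1 was at 283.5 ± 47.9 (SD, n = 5) in F1 and Grifin at 556.9 ± 116, both between the parents, and Cbr1 was at 386.8 ± 265.

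**Figure D4:**
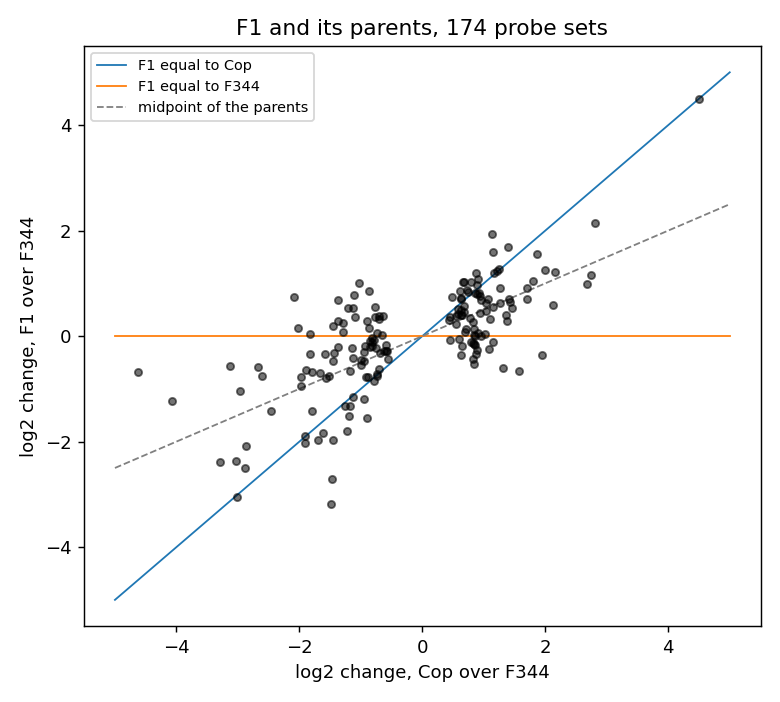
Log2 change of F1 over F344 against that of Cop over F344, at the 174 probe sets that differed between Cop and F344. Lines mark F1 equal to Cop, F1 equal to F344 and the midpoint of the parents. On a scale from 0 at F344 to 1 at Cop the median position is 0.45, and 99 probe sets lie between the parents.

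Epithelial and milk genes were higher in F1 than in the parental mean and muscle, fat and respiratory genes lower. Of 9 milk protein genes 7 were higher, 8 when adjusted over the list alone, among them Csn3 at 2.51 and Csn1s1 at 1.24 (camera adjusted p = 3.4e-05, and adjusted p = 0.13 with an estimated correlation). Of 10 luminal markers 8 were higher, 9 when adjusted over the list alone, with Krt19 at 0.94 and with Lcn2 at 2.25, whose signal of 1694 ± 652 in F1 was near that of Cop (adjusted p = 0.00015, and adjusted p = 0.13 with an estimated correlation). Of 10 basal markers 8 were higher on both counts, with Actg2 at 1.18 and Cnn1 at 0.90 (adjusted p = 0.00075, and adjusted p = 0.1 with an estimated correlation). Of 21 fibroblast and matrix genes 10 were higher and 1 lower, 11 and 1 when adjusted over the list alone, with the proteoglycan Bgn at 0.86 (adjusted p = 0.00093, and adjusted p = 0.13 with an estimated correlation). Of 35 ribosomal protein genes 17 were higher and 1 lower, 20 and 1 when adjusted over the list alone, with Rpl6 at 0.98 and Rpl23 at 0.78 (adjusted p = 2.5e-06, and adjusted p = 0.13 with an estimated correlation). Under quantile normalization the fibroblast list (adjusted p = 0.078) and the ribosomal list (0.37) missed the threshold.

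Of 18 muscle genes 14 were lower in F1 and 18 when adjusted over the list alone, with the enolase gene Eno3 at least 8.46-fold lower and the calsequestrin gene Casq1 at -1.83 (median -2.32, camera adjusted p = 1.3e-06, and adjusted p = 0.24 with an estimated correlation). Of 34 genes of oxidative phosphorylation and beta oxidation 20 were lower, 21 when adjusted over the list alone, with Uqcrc2 at -1.75, Cox5b at -1.15 and Ndufa5 at -1.09 (adjusted p = 2.5e-06, and adjusted p = 0.1 with an estimated correlation). Of 17 adipocyte genes 12 were lower and 1 higher, 13 and 1 when adjusted over the list alone, with the fat cell regulator gene Pparg at -1.52 and the acyl-CoA synthetase gene Acsl1 at -0.94, while the 1 higher gene, Cfd (0.55), was at -0.007 under quantile normalization (adjusted p = 0.0012, and adjusted p = 0.18 with an estimated correlation). Of 21 genes of fatty acid and sterol synthesis 9 were lower, 9 lower and 1 higher when adjusted over the list alone, with the fatty acid synthase gene Fasn at -2.14, Me1 at -1.98 and Insig1 at -1.44 (adjusted p = 0.0053, and adjusted p = 0.24 with an estimated correlation). Of 27 genes of xenobiotic metabolism 15 were lower and 1 higher, 16 and 1 when adjusted over the list alone, with the glutathione transferase gene Gsta1 at -1.73, Ephx1 at -1.64 and the acetyltransferase gene Nat1 at -1.33 (adjusted p = 6.8e-05, and adjusted p = 0.13 with an estimated correlation). The score of the muscle genes was -1.26 ± 0.85 (SD, n = 5) in F1, that of the fat cell genes -0.27 ± 0.29 and that of the luminal markers 0.39 ± 0.22, or 0.30 without Lcn2. The list of DNA repair had a median of 0.10 and a mean of -0.11 and missed the threshold.

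Cop and F1 were set against F344, BUF/N and WF to ask which genes follow resistance. For that question the groups are the units and not the arrays, and F1 shares a parent with each side. The p-values of this contrast, for genes and for lists, measure the spread between arrays and do not test resistance. Another split of the same groups, with Cop and F344 on the first side, called 1930 probe sets. By the rule that no array of one side overlapped the other, 3 genes were named. Klc1, a kinesin light chain gene, was at 170.1 ± 20.9 (SD, n = 5) in Cop and 170.1 ± 41.5 in F1, and between 92.98 ± 9.78 and 96.1 ± 7.09 in the 3 susceptible strains (log2 change 0.83, SE 0.096, adjusted p = 3.72e-07), but its other probe set gave 0.03. The lysosomal protease gene Ctsc was lower (-0.88, and -0.47 on its other probe set). Hs6st1 was lower too, mostly through Cop, whose arrays were all at the floor, so that its log2 change of -2.80 is no exact size, while F1 was at 283.5 ± 47.9 and F344 at 455.4 ± 66.9. In all, 833 probe sets passed, 378 higher in Cop and F1 and 455 lower, with 18 and 41 of them beyond 2-fold, and 544 without F1 2 and F1 3. The balance of directions turned with the scaling, to 380 higher and 325 lower with quantile normalization and 524 and 341 with centring. For RT1-Bb, 1 probe set was high in Cop (958.4 ± 113), F344 (1168 ± 91.4) and F1 (1145 ± 265) and low in BUF/N (62.1 ± 12) and WF (50.7 ± 20.3), and another was high in BUF/N (421.8 ± 140) and WF (664.3 ± 328) alone.

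Growth factor and xenobiotic genes were among the lists lower in the mean of Cop and F1. The mean score of growth factors was -0.15 ± 0.15 (SD, n = 5) in Cop and -0.23 ± 0.38 in F1. In F1 this mean came from F1 2 (-0.627) and F1 3 (-0.615). F1 1, F1 4 and F1 5 were at -0.094, 0.005 and 0.204. For p53 and apoptosis the mean score was -0.19 ± 0.1 in Cop and -0.19 ± 0.22 in F1, where F1 5 was at 0.158. Other lists differed between Cop and F1. The xenobiotic score was 0.14 in Cop and -0.5 in F1, against 0.17 in F344, 0.11 in BUF/N and 0.19 in WF. The luminal score was -0.53 in Cop and 0.39 in F1, and the ribosomal score -0.06 and 0.3. Of 30 genes of growth factors, IGF and TGF-beta 10 were lower and 0 higher, 13 and 1 when adjusted over the list alone, with the receptors Erbb2 at -0.69 and Erbb3 at -0.76 (camera adjusted p = 0.0076, and adjusted p = 0.5 with an estimated correlation). Of 27 genes of xenobiotic metabolism 5 were lower, 6 when adjusted over the list alone, with Cbr1 at -2.42 and Ephx2 at -1.26 (adjusted p = 0.014, and adjusted p = 0.5 with an estimated correlation). Of 12 genes of p53 and apoptosis 4 were lower, 5 lower and 1 higher when adjusted over the list alone, with the cyclin gene Ccng1 at -1.28 and Casp6 at -0.94 (adjusted p = 0.03, and adjusted p = 0.45 with an estimated correlation). The list missed the threshold without F1 4 (0.06). Of 10 luminal markers 6 were lower and 1 higher, 8 and 2 when adjusted over the list alone, with the adhesion gene Epcam at -0.91, Cldn3 at -0.86 and Lcn2 at 1.07 (adjusted p = 0.022, and adjusted p = 0.5 with an estimated correlation). This call ended without Cop 4 or F1 4 (0.053 each). Of 4 mast cell genes Cma1 (0.55) and Cpa3 (0.66) were higher on both counts (adjusted p = 0.014, and adjusted p = 0.45 with an estimated correlation). Of 35 ribosomal protein genes 8 were higher, 11 when adjusted over the list alone (adjusted p = 0.00027, and adjusted p = 0.49 with an estimated correlation), but under quantile normalization their median turned from 0.22 to -0.013 (0.63). Of 21 genes of fatty acid and sterol synthesis 5 were lower and 1 higher, 8 and 1 when adjusted over the list alone (adjusted p = 0.033, and adjusted p = 0.5 with an estimated correlation). That call ended without F344 1 (0.09), F344 3 (0.052), F344 5 (0.06), BUF/N 2 (0.06), BUF/N 3 (0.053), BUF/N 5 (0.066), WF 1 (0.054), WF 3 (0.056), F1 1 (0.096), F1 2 (0.055) or F1 4 (0.099). Without F1 2 and F1 3 together, the growth factor (0.096), xenobiotic (0.092) and fatty acid (0.083) calls ended. The secretoglobin list had a median of -0.09 and a mean of 0.06 and missed the threshold.

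Several genes were set in advance for their part in mammary development or carcinogenesis. Prlr was at 335 ± 38.9 (SD, n = 5) in Cop and 591.7 ± 82.8 in F344 (log2 change -0.82, adjusted p = 0.0284), -0.94 in Cop against the mean of the other 4 strains, and -0.56 in Cop and F1 against the susceptible strains. The other probe sets of Prlr gave -0.57 and -0.64 against F344 and -0.23 and -0.09 in the last contrast, none of which passed, and the named one missed the threshold there without F1 2 and F1 3 (0.051). The call against F344 ended without Cop 1 (0.063), Cop 2 (0.086), Cop 4 (0.053), F344 1 (0.071), F344 4 (0.094) or F344 5 (0.05), and with no filter. None of the others passed between Cop and F344, with log2 changes of -0.25 for the transcription factor Stat5a, -1.03 for Csn2, -0.59 for Wap, -0.17 for the lactalbumin Lalba, -0.34 for the progesterone receptor Pgr, 0.66 for Cyp1b1, which activates carcinogens, -0.01 for Gstp1, 0.11 for the repair gene Mgmt, 0.01 for Nqo1, -0.10 for the cyclin Ccnd1, 0.40 for Igf1 and 0.35 for Tgfb1. In F1 against its parents, Lalba (1.36), Wap (2.76) and Stat5a (0.67) were higher and Cyp1b1 (-1.13), Mgmt (-1.29), Nqo1 (-1.69) and Tgfb1 (adjusted p = 0.00266) lower. The other probe set of Mgmt gave 0.12, and Stat5a (adjusted p = 0.052) and Tgfb1 (0.25) missed the threshold without F1 2 and F1 3. Wap was lower in F344 (-2.68) and higher in ACI (2.40) than in the mean of the other 4 strains, the latter not without ACI 2 and ACI 5 (0.12). Igf1 was higher in Cop (0.50) and lower in BUF/N (-0.52), and Ccnd1 was lower in WF (-0.81), though further probe sets of Igf1 gave 0.53, 0.22, 0.03 and -0.01 in Cop. In F1 against its parents the named probe sets of Prlr (0.29), Ccnd1 (-0.18) and Igf1 (-0.33) did not pass, while others did for Prlr (0.89 and 0.64), Ccnd1 (0.74) and Igf1 (1.05 and -1.30). The oestrogen receptor gene Esr1, Cyp1a1, the aromatase gene Cyp19a1 and Cdkn1a had no probe set that passed the filter, and Hras was not among the probe sets with 1 symbol.

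Some calls of these genes lay near the threshold and ended when any 1 of several arrays was left out. Csn2 was lower in F344 than in the mean of the other 4 strains (-2.37), but not without F344 2 (adjusted p = 0.061), F344 3 (0.15), F344 4 (0.12), F344 5 (0.11), ACI 2 (0.051), BUF/N 1 (0.05) or BUF/N 3 (0.052). Gstp1 was lower in ACI (-0.48), but not without ACI 2 (0.081) or ACI 5 (0.16), and Ccnd1 higher (0.67), but not without ACI 1 (0.076), ACI 2 (0.054) or ACI 4 (0.11). Stat5a was higher in BUF/N (0.50), but not without BUF/N 2 (0.088), BUF/N 3 (0.11) or BUF/N 5 (0.066), and Cyp1b1 lower (-0.78), but not without BUF/N 1 (0.065) or BUF/N 3 (0.13). Prlr was higher in WF (0.68), but not without WF 2 (0.074) or WF 5 (0.052). For Wap the mean of Cop and F1 was below that of the susceptible strains (-1.48). That call ended without F1 1 (0.063) or F1 2 (0.052). Cop and F1 did not share this difference, since Wap in F1 was above the mean of its parents. The milk protein score was -1.38 in Cop and 0.87 in F1, against -0.86 in F344, 0.82 in BUF/N and 0.03 in WF.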

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

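The tests of the 3 patterns weighed below were chosen after the data and the patterns had been seen. For those on F1 2 and F1 3 and on the 4 milk protein genes the result of the test itself was seen before its bounds were set. Those with a luminal score without Lcn2 were added after the results with Lcn2 were seen, with the same bounds. For the others the bounds were set before the test was run. Of 155 groups of 5 values examined for a single array far from the rest, 9 had one, and chance alone gives this in about 1 in 20 groups. F344 1 stood apart for Tmtc3 with a signal of 73.6 (nearest array 57.2), for Hs6st1 with 569.3 (449.1), for Spock2 with 137.6 (109.4) and for the casein gene Csn2 with 572.1 (152.8). Csn2 also had 1 high Cop array, Cop 5 at 550.5, with the next at 46.3. Ephx2 was at 56.8 in Cop 2, with the next Cop array at 13.3, and Alb at 242.5 in Cop 1, with the next at 156.8. Acaa2 was at 1086 in ACI 4, with the next ACI array at 779.6. The ratio of 3' to 5' signal of the GAPDH control was 1.353 in WF 1, with the next WF array at 0.9992.

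Groups drawn from the same arrays at random were compared with the real ones. No other split reached the real count for the difference among the 6 groups, with 2613 probe sets against at most 128 in the other splits and 1 split of 100 as high, the real one. The same holds for Cop against F344 (174, highest other 15), ACI (382, 41), BUF/N (1172, 209) and WF (647, 83), and for F1 against Cop (1325, 1014), F344 (1596, 957) and the mean of its parents (1774, 1173). It holds for the probe sets apart in Cop (36, 0), F344 (25, 0), ACI (37, 0), BUF/N (34, 0) and WF (19, 4). The other splits mixed the real groups, which widens the spread within a group, so low counts were likely in them. The splits thus test only against no difference at all, and the labels do not say that the arrays are independent samples. For Cop and F1 against F344, BUF/N and WF there are 10 splits of the 5 groups, too few to exclude chance, and 5 of them called as many probe sets. The real split called 833 and the highest other 1930, for Cop and F344 against the rest, which points to a structure of the samples whose cause was not tested.

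F1 lay away from the mean of its parents at 1774 probe sets. Without F1 2 and F1 3, 1032 passed, among them 787 of the 1774, so these arrays do not make all of it, though most of the calls were lost without them and fewer arrays also give less power. The scale of the midpoint does not make it, since 1744 of the 1774 were among the 1762 that passed against the mean of the parental signals. With the scores of muscle, fat and luminal epithelium as covariates 3 passed, and 3 with a luminal score without Lcn2, so a different content of these tissues is consistent with the pattern. That test also lost precision, because the median standard error rose from 0.182 to 0.302 while the changes shrank to a median ratio of 0.58. Without Lcn2 in the score the median standard error was 0.278. Between Cop and F344, 159 probe sets still passed with the covariates and 60 without Lcn2 in the score, against 174 with no covariates. An effect of the hybrid genotype on the gland would change the same scores and was not tested.

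The clock genes of ACI were lower by a median of -0.95, and by -1.06 without ACI 2 and ACI 5, so these arrays do not make the difference alone. Collection at another phase of the day would lower Dbp and Per2 and raise genes of the opposite phase, but 0 such genes were measured and 3 were needed to decide. A difference of the strain in the clock itself is open as well, and the labels give no time of collection. The clock score was also low in F1 (-0.24 ± 0.2, SD, n = 5), below Cop (0.16) and F344 (0.34). Dbp was at 140.1, 137.2 and 155.8 in F1 1, F1 4 and F1 5. In F1 2 and F1 3 it was at 325.2 and 313.3, so its level also varied among samples with the same label.

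Milk protein genes were lower in Cop by a median of -1.08, by -0.17 with the score of luminal epithelium as a covariate and by -0.13 when this score left out Lcn2, which was higher in Cop unlike the other markers, so less epithelium in the Cop samples is consistent with the pattern of the list. Of the genes that passed, 4 of 4 kept a 95% interval below 0, and 3 of 4 without Lcn2 in the score. The 3 were Csn3 at -1.44 (-2.38 to -0.49), Wap at -2.46 (-4.24 to -0.68) and Muc1 at -0.82 (-1.41 to -0.24). Csn2 at -1.57 (-3.83 to 0.68) did not. The test cannot tell whether less epithelium makes the whole difference of these genes. The score, a mean of 9 marker genes or 8 without Lcn2, is an inexact measure of epithelium, and the 4 genes were chosen as lower in Cop. Prlr was lower by -0.82 (-1.27 to -0.36) with the covariate and by -0.69 (-1.23 to -0.14) without Lcn2 in it, against -0.94 with no covariate. In F344 the score of the milk protein genes was low as well (-0.86 ± 0.36, SD, n = 5) while Prlr did not pass there (0.08), so a link between Prlr and these genes is left open. The stage of the cycle is not in the labels and could give the same pattern.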

How the results depend on the processing

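Leaving out F1 2 and F1 3, ACI 2 and ACI 5 or all 4, and the midpoint of signals, were alternatives added after the data were seen, and the others were set before the data were examined. Of the gene results recomputed, 24867 kept direction and side of the threshold, 1242 lost the threshold, 61 gained it and 91 changed sign. Of the list results 2709 were kept, 112 weakened and 1 changed sign, and of the counts 696 stayed within 1.5-fold and 48 did not. With replicate number as a block all 16 counts stayed within 1.5-fold, for example 174 for Cop against F344 and 1732 for F1 against its parents. The cause was not tested for any change below unless one is given. Signals near background limit what can be seen, since by construction the floor hides any difference below it.

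Array weights gave 479 for Cop against F344, 1254 for Cop and F1 against F344, BUF/N and WF, and 88 apart in Cop, 82 in F344, 124 in BUF/N and 39 in WF. The pools as sixth samples gave 584 for Cop against ACI, 60 apart in Cop and 59 in ACI. Without F1 2 and F1 3 there were 626 for Cop against ACI, 922 for F1 against F344, 1032 for F1 against its parents, 544 for Cop and F1 against F344, BUF/N and WF, and 63 apart in Cop, 65 in ACI and 29 in WF. Without ACI 2 and ACI 5 there were 228 for Cop against ACI and 13 apart in ACI. Without all 4 there were 290 for Cop against F344, 1007 for Cop against WF, 1049 for F1 against F344, 60 apart in Cop and 29 in WF. With only the arrays compared there were 292 for Cop against F344 and 661 for F1 against Cop. At a threshold of 0.01, which by construction calls fewer, 12 were apart in Cop, 10 in F344, 14 in ACI, 15 in BUF/N and 9 in WF. With an estimated correlation 1 of 61 list calls remained. With no filter the pools and samples correlated at r = 0.566.

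Leaving out single arrays gave 213 to 451 for Cop against ACI (213 without Cop 1, 217 without Cop 2, 226 without ACI 2). It gave 19 to 48 apart in Cop (22 without Cop 1, 19 without Cop 2, 20 without Cop 4 or F344 4), 16 to 26 in F344 (16 without F344 5) and 22 to 57 in ACI (22 without ACI 2 or ACI 5, 57 without ACI 3). It gave 21 to 72 in BUF/N (22 without BUF/N 3 or BUF/N 4, 72 without WF 1, 21 without WF 4) and 11 to 23 in WF (11 without WF 5). Fewer arrays give less power by construction. The other counts stayed within 1.5-fold, with 118 to 193 for Cop against F344, 1353 to 2019 for F1 against its parents and 567 to 1198 for Cop and F1 against F344, BUF/N and WF.

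The ribosomal list in Cop and F1 against F344, BUF/N and WF turned from 0.22 to a median of -0.013 under quantile normalization, and Cfd in F1, which had passed the test, from 0.55 to -0.007. Wap in Cop against F344 turned from -0.59 to 0.029 with the floor at the 40th percentile. In F344 against the other strains quantile normalization gave 0.009 for Stat5a, -0.052 for Gstp1 and -0.037 for Igf1, and in ACI 0.022 for Lalba and 0.022 for Igf1. Centring gave 0.009 for Stat5a, 0.029 for Lalba and 0.007 for Ccnd1 in F344 and 0.06 for Gstp1 in Cop. Array weights gave 0.007 for Lalba, -0.009 for Gstp1 and -0.022 for Igf1 in F344, -0.272 for Cyp1b1 in ACI (from 0.16) and 0.06 for Pgr (from -0.29) in Cop and F1 against F344, BUF/N and WF. The pools as sixth samples gave 0.012 for Gstp1 in Cop and -0.013 for Igf1 in F344. Without F1 2 and F1 3, and without all 4 arrays, Stat5a was at -0.027 and Mgmt at 0.006 (from -0.39) in Cop and F1 against F344, BUF/N and WF. Without ACI 2 and ACI 5, and without all 4 arrays, Lalba was at 0.008 and Gstp1 at -0.047 in F344, and Cyp1b1 at -0.293 (from 0.16) and Tgfb1 at 0.02 (from -0.29) in ACI. All other changes of sign in this paragraph started from values between -0.061 and 0.025.

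When single arrays were left out, Cop against F344 ran from -0.062 to 0.047 for Gstp1, from -0.161 to 0.165 for Nqo1, from -0.32 to 0.012 for Lalba and from -0.228 to 0.071 for Ccnd1. In F344 the ranges were -0.054 to 0.03 for Igf1, -0.39 to 0.03 for Cyp1b1, -0.187 to 0.066 for Ccnd1, -0.044 to 0.065 for Gstp1 and -0.112 to 0.059 for Lalba. In ACI they were -0.15 to 0.121 for Lalba and -0.04 to 0.436 for Cyp1b1. Gstp1 ran from -0.047 to 0.059 in Cop and from -0.153 to 0.06 in F1, Cyp1b1 from -0.114 to 0.148 in WF, and Nqo1 from -0.206 to 0.081 in BUF/N. In Cop and F1 against F344, BUF/N and WF, Stat5a ran from -0.077 to 0.083 and Cyp1b1 from -0.012 to 0.135. Centring raised the percentage of calls higher in Cop from 47.5 to 58.2 against BUF/N and from 43.7 to 58.1 against WF, and quantile normalization to 54 and 50.8. For Cop and F1 against F344, BUF/N and WF it went from 45.4 to 60.6 with centring and 53.9 with quantile normalization.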

Other observations

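None of the values in this part were tested after the result was seen. Brown fat genes had a score of 0.52 ± 0.32 (SD, n = 5) in F344 and -0.39 ± 0.36 in WF.

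The 2 pools belong to no group of single samples. Each pool correlated with the arrays of its own strain at r = 0.944 to 0.98 over the tested probe sets. The ratios of the pools were 2.56 for Tmtc3, 1.91 for Alb, 1.66 for Kif13a, -3.09 for Grifin and -1.50 for H19. No 2 arrays of the series were identical. The first 3 principal components held 21.6%, 15.3% and 11.1% of the variance. On the first, F1 2 and F1 3 lay at -44.8 and -47.2 and the other arrays between -24 and 27.3. On the third, ACI 2 and ACI 5 lay at -40 and -42.7 and the other arrays between -10.7 and 12.6. These components thus reflect single arrays as well as groups.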
